A study of Mus musculus with 8 samples.

How the data were processed

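Gene expression was measured in whole mouse embryos at embryonic day 11.5 from matings of mice that carry a low-expression allele of Ott1, the gene now named Rbm15. Per the labels, each of the 8 arrays holds RNA of 1 embryo, genotyped as wild type (embryos 11 and 13), heterozygous (embryos 3, 10 and 15) or homozygous for the allele (embryos 2, 7 and 16). The replicates are separate embryos. Per the labels' protocols, embryos were snap-frozen, total RNA was purified, and biotin-labelled cRNA was made by the CodeLink procedure and hybridised to one-colour oligonucleotide arrays.

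Each deposited array file holds a scanner intensity per spot. Per the file headers and the values themselves, the intensity used here is the spot mean minus the local background median, so it was already background-corrected. The array files also hold a scaled intensity, and the deposited value table of the series holds the same scaled intensities. Set against the array files, that table differed by at most 5e-08. Each scaled value is the intensity divided by 1 factor per array, between 48.64 and 88.45, so its scale is linear and its centre is close to the array median. The scanner software, its settings and any genome build are not given in the sources used here.

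An array carried 35587 spots, of which 34967 were gene probes, 320 negative control spots and 300 positive control spots. Control spots were left out, and gene spots that the scanner software marked as contaminated, irregular or masked were set missing. Saturated spots were kept. Between 206 and 1634 gene probes per array were left out in this way, and between 22526 and 26619 were above background. The number of arrays, 2 or 3 per genotype, limits the precision of every value.

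The intensities were quantile normalized between the 8 arrays with limma 3.58.1 in R 4.3.3. A floor was then set at the 5th percentile of the positive normalized values, an intensity of 4.5 or 2.17 on the log2 scale, and log2 was taken. Probes above background on all arrays of at least 1 genotype were tested, which left 23389 probes. Linear models were fitted per probe with limma's lmFit and eBayes, two-sided, and p-values were adjusted by Benjamini-Hochberg over all tested probes, with a threshold of 0.05. A model of 3 genotype means over all 8 arrays gave homozygous against wild type, heterozygous against wild type and homozygous against heterozygous. A second model compared the 3 homozygous with the 5 other embryos. These comparisons share arrays, so they are not independent of each other. Where every array of a group lay at background, the fold is given as a lower bound, set against the lowest signal among probes above background on those arrays.

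Probes were named through their RefSeq accession in a list of genes of the mouse assembly GRCm38.p6, used only for names, for which genes neighbour each other and for the chromosome they lie on. A single symbol was found for 14763 gene probes, and 20204 stayed unnamed. Unnamed probes are given by the identifier in the files. No probe was matched to Rbm15 itself, and 1 probe was matched to its paralog Rbm15b.

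The groupings, the tests, the 33 gene lists and the rule for named genes were fixed before the data were examined. The rule named Rbm15b in every comparison. It also named up to 12 genes per direction with the largest change among those past the threshold without overlap between groups, or, where fewer than 5 passed, the 5 with the smallest p. It allowed up to 4 members of each list that passed, and up to 3 members with the highest mean of the lists of other tissues. Which of those members are printed was chosen after their values were seen. For Hbb-y, Eif2s3y, Kdm5d and Tfap2c only levels are given, and Hba-a1 is not printed. This choice was made after the alternatives had been run and the sign of some of their changes had been seen to turn. For a gene with several probes, the probe with the highest mean stood for the gene in the lists. Lists were tested against all other probes without a missing value (21788) with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and fry, a rotation test of the list alone, were alternatives. A score per embryo, the mean over a list's genes of the log2 value minus that gene's mean over the embryos, was compared between the 3 homozygous and the 5 other embryos by an exact two-sided permutation test over the 56 splits, whose smallest possible p is 0.0357.

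The alternatives were median scaling, cyclic loess, the deposited value table, other floors, normexp with an offset of 50, other filters, array weights, a trended robust prior, 1 probe per gene, a Y-linked covariate, a fit of only the groups compared, and each embryo left out in turn. Leaving out a wild type embryo leaves 1, which is then assumed to vary like the other groups. Keeping the marked spots, and leaving out embryos 10 and 16 together, were added after the data were seen.

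The method was tested on simulated data with the real probe means, in which 200 of the 23389 probes were changed, 100 by 1 and 100 by 2 on the log2 scale. For homozygous against the other embryos, 65% of the smaller and 93% of the larger changes were recovered, with 5 false calls. For homozygous against wild type the shares were 40% and 84% with 8 false calls, for heterozygous against wild type 44% and 84% with 8, and for homozygous against heterozygous 54% and 85% with 9. In the list test, 1 list raised by 0.5 was called, and 0 of the 32 other lists were. The simulated probes varied independently of each other, while the real hypoxia and glycolysis list had an estimated correlation of 0.427. The simulation therefore cannot show how often camera calls lists of correlated genes falsely.

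Tables were read with Python 3.11.15 and the R package data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 and numpy 2.4.6.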

Results

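The study asked how a lowered dose of Rbm15 (Ott1), an RNA-binding protein of the Spen family with roles in m6A methylation, splicing and mRNA export, alters gene expression in the mouse embryo. One-colour CodeLink arrays were read for 2 wild type, 3 heterozygous and 3 homozygous whole embryos at E11.5. The median background-corrected intensity of an array lay between 48.28 and 57.63 in the 5 wild type and heterozygous embryos. It was 61.45, 61.52 and 87.93 in homozygous embryos 2, 7 and 16. All 3 homozygous arrays were thus brighter than the 5 others before normalization, so array brightness cannot be told apart from homozygosity. Log2 values of pairs of arrays correlated at 0.973 to 0.990 among the 7 other embryos and at 0.956 to 0.967 with embryo 16. In a principal component analysis the first component held 39.7% of the variance, with embryo 16 at 74.4 and the other embryos between -25.1 and 7.31. The second held 20.3% and set homozygous embryos 2 and 7 and heterozygous embryo 3 (-38.1, -26.6 and -14.3) apart from the others (10.7 to 20.2). The mean of 4 Y-linked probes was 5.47, 5.11 and 5.40 in embryos 3, 15 and 16 and between 6.33 and 6.57 in the 5 others, and the embryos carry no sex label. The Y-linked gene Eif2s3y was at 4.39 and 4.48 in embryos 3 and 15, against 9.17 to 9.69 in the 5 others, and was missing in embryo 16. The Y-linked gene Kdm5d was at 5.90 in embryo 16, against 6.45 and 6.50 in embryos 3 and 15. If low levels mark females, both wild type embryos were male, and heterozygous embryos 3 and 15 and homozygous embryo 16 were female. Heterozygous against wild type is then partly confounded with sex, and so, to a lesser degree, are homozygous against wild type and homozygous against heterozygous.

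The targeted gene could not be checked, because no probe was matched to Rbm15, and its level is not analysed here. Whether any of the 20204 unnamed probes, among them those that fell in homozygous embryos, measures Rbm15 is not known. Its paralog Rbm15b, which also recruits the m6A methyltransferase complex, had a log2 level of 10.55 ± 0.04 (SD, n = 2) in wild type, 10.63 ± 0.06 (n = 3) in heterozygous and 10.87 ± 0.06 (n = 3) in homozygous embryos. Its log2 difference between homozygous and the other embryos was 0.28 (SE 0.08, limma adjusted p = 0.163) and did not pass. The difference was -0.02 under median scaling and -0.05 in the deposited value table. The median of all probes also lay lower there, at -0.22 and -0.25 against -0.06, so Rbm15b stayed above it.

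In homozygous embryos against the 5 others, 3 genes that lie near each other on chromosome 4 fell together. Ccdc28b, a modifier of Bardet-Biedl syndrome, fell by 4.33 on the log2 scale (SE 0.22, adjusted p = 0.000182), from 8.57 ± 0.12 (SD, n = 5) to 4.24 ± 0.55 (n = 3). It was above background in only 1 of the 3 homozygous embryos, and its change ranged from -4.58 to -2.55 over the alternatives. Trnau1ap, which binds the selenocysteine tRNA, fell by 1.86 (SE 0.12, 3.63-fold lower, adjusted p = 0.000602), and Trim62, a ubiquitin ligase, fell by 2.34 (SE 0.24, 5.05-fold lower, adjusted p = 0.0163). Chst15, a chondroitin sulfotransferase, rose by 1.02 (SE 0.10, 2.03-fold, adjusted p = 0.013). The lysosomal galactosidase Glb1 rose by 0.71 (SE 0.09, 1.63-fold, adjusted p = 0.0421), and the cytokine receptor Crlf2 rose by 1.26 (SE 0.17, 2.39-fold, adjusted p = 0.0473). The arrestin-domain gene Arrdc4 fell by 0.72 (SE 0.08, adjusted p = 0.0223). Rpp40, a subunit of RNase P, was not above background in any homozygous embryo and was above it in 3 of the 5 others, with a level at least 1.65-fold lower in homozygous embryos (adjusted p = 0.0356). The defensin gene Defa31, the cone channel gene Cnga3, the transcription initiation factor gene Taf9b and the stem cell marker Dppa5a fell by 1.58, 0.94, 0.83 and 1.27, each with an adjusted p of 0.0421. Cnga3 and Dppa5a were each above background in only 1 of 3 homozygous embryos, and Cnga3 in 3 of the 5 others, and over the alternatives their changes ranged from -1.03 to -0.274 and from -1.6 to -0.457. Among probes without a symbol, GE114254 was at least 20.4-fold lower (adjusted p = 0.000182) and GE1437096 fell by 3.08 (SE 0.22, adjusted p = 0.00142), while GE1394148 was at least 4.61-fold higher (adjusted p = 0.0165) and GE1442542 rose by 1.41 (SE 0.16, adjusted p = 0.0229). The unnamed probe GE102200 was also lower, at 7.02 ± 0.08 (SD, n = 3) in homozygous embryos. It was at 9.15 ± 0.18 (n = 3) in heterozygous and 9.42 ± 0.14 (n = 2) in wild type embryos. Zfp451 (0.70) and Vegfa (1.57) were higher in homozygous embryos and did not pass, at an adjusted p of 0.0574 each.

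**Figure D1:**
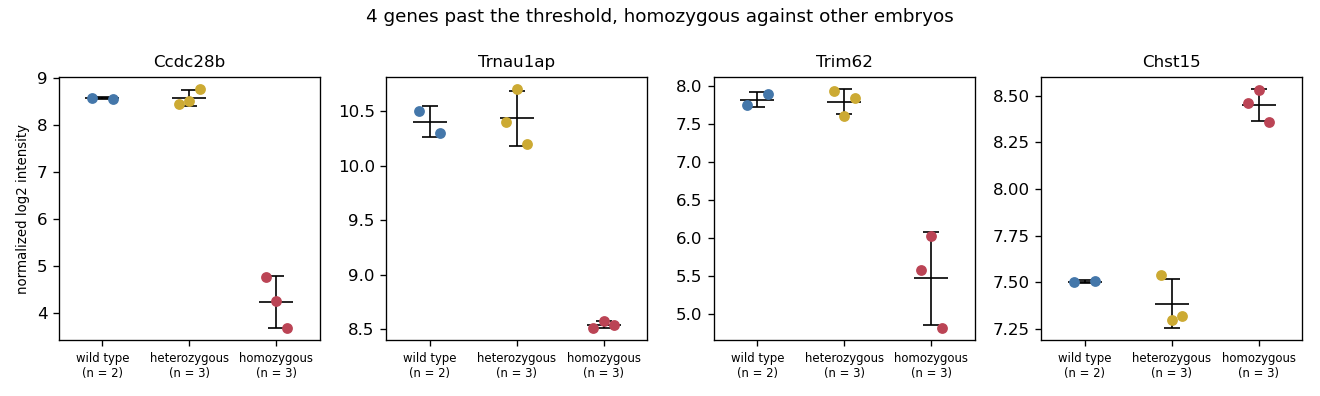
Normalized log2 intensity of Ccdc28b, Trnau1ap, Trim62 and Chst15 in each embryo, by genotype. Each point is 1 embryo, the wide bar is the mean and the whiskers are 1 SD; the axes do not start at 0. The 3 homozygous embryos lie apart from the 5 others in each panel, with Ccdc28b at 4.24 ± 0.55 (n = 3) against 8.57 ± 0.12 (n = 5).

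In this comparison 25 of 23388 probes passed the threshold, 7 higher and 18 lower. In all 25 the homozygous values did not overlap the others, but picking by a small p favours such probes, so this adds no support. Among probes not so picked, chance gives it in 3.57%. At an unadjusted p under 0.05 there were 4678 probes, 20% of those tested. The count moved to 314 without homozygous embryo 7, 39 without heterozygous embryo 10, 14 without heterozygous embryo 3, 6 without wild type embryo 11, and 5 each without wild type embryo 13 or heterozygous embryo 15. Under cyclic loess 18 of 39 calls were higher. Ccdc28b, Trnau1ap, GE114254 and GE1437096 passed under every alternative run. The call of each other gene named above, GE102200 not counted, was lost under some. Trim62 passed in 18, Chst15 in 16, Arrdc4 in 14, Glb1 in 11 and Crlf2 in 10 of 22 alternatives, and Cnga3 in 6 of 21.

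Genes of hypoxia and glycolysis were higher together in homozygous embryos. Of 23 measured members 17 rose and 0 fell when adjusted over the list alone, none passed over all genes tested, and 22 had a positive sign. Vegfa, the vascular growth factor, had a log2 difference of 1.57 (SE 0.22), hexokinase Hk2 1.20 (SE 0.19, adjusted p = 0.0705), the mitophagy receptor Bnip3 1.35 (SE 0.22, adjusted p = 0.0708) and the oxygen sensor Egln1 0.70 (SE 0.10, adjusted p = 0.0574). The median member was 1.49-fold higher, and camera called the list (adjusted p = 1.98e-15), a call lost with an estimated correlation (adjusted p = 0.649). The list score was 0.43 ± 0.29 (SD, n = 3) in homozygous, -0.23 ± 0.15 (n = 3) in heterozygous and -0.30 ± 0.02 (n = 2) in wild type embryos. Embryo 16 had the highest score, 0.76, against 0.27 and 0.26 in embryos 2 and 7. The score differed by 0.69 between homozygous and other embryos, at the smallest exact permutation p that the design allows (0.0357), which was 0.168 after adjustment over the 33 lists.

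**Figure D2:**
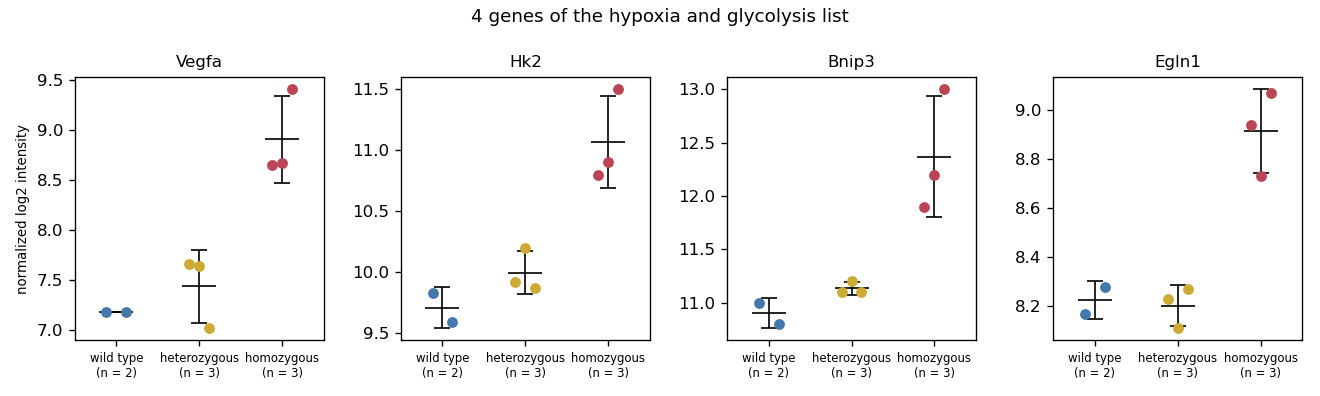
Normalized log2 intensity of Vegfa, Hk2, Bnip3 and Egln1, members of the hypoxia and glycolysis list, in each embryo. Each point is 1 embryo, the wide bar is the mean and the whiskers are 1 SD; the axes do not start at 0. All 3 homozygous embryos lie above the 5 others in each panel, and none of the genes passed the threshold over all probes.

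Other lists also passed camera in this comparison. The integrated stress response, the translational and amino acid response to cell stress, was higher (16 measured, 3 risen adjusted over the list alone, 0 over all genes, adjusted p = 9.4e-05, and 0.649 as the adjusted p with an estimated correlation). Its member Chac1, which degrades glutathione, was at least 3.94-fold higher without passing over all genes (adjusted p = 0.137), and the mitochondrial serine enzyme Shmt2 and the lipoprotein receptor Vldlr had log2 differences of 0.61 (SE 0.16) and 1.16 (SE 0.31). Without embryo 16 these values were at least 2.19-fold for Chac1, 0.383 for Shmt2 and 0.719 for Vldlr. The score of this list was 0.72 in embryo 16 and 0.15 and 0.00352 in embryos 2 and 7. Endothelial genes were higher, with Vwf at 0.88 (SE 0.20), Cd93 at 0.62 (SE 0.14) and Sox7 at 0.70 (SE 0.17), while the angiopoietin gene Angpt2 was at -0.50 (SE 0.13). Of 25 measured members 5 rose and 1 fell adjusted over the list alone and 0 over all genes (adjusted p = 0.00239, and adjusted p = 0.649 with an estimated correlation). Without embryo 16 the endothelial call was lost (adjusted p = 0.146). The endothelial score was 0.273 in embryo 16 and 0.0621 in embryo 7, while that of homozygous embryo 2, -0.0666, was below those of embryos 10, 13 and 15. Cardiomyocyte genes were higher, with Ankrd1, above background in 3 of the 5 other embryos, at 1.22 (SE 0.41) and the ventricular light chain gene Myl3 at 0.42 (SE 0.16), while the sarcolipin gene Sln was at -0.67 (SE 0.23). A positive sign was held by 20 of the 24 measured cardiomyocyte members, and the call was lost without embryo 3 (0.0921) or embryo 16 (0.0579). Among them 0 passed adjusted over the list alone or over all genes (adjusted p = 0.00969, and adjusted p = 0.68 with an estimated correlation). The cardiomyocyte score of heterozygous embryo 10, 0.189, was above those of all homozygous embryos (0.148, 0.0898 and 0.123).

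Myc targets and ribosome biogenesis genes were higher as a list (24 measured, 2 risen adjusted over the list alone, 0 over all genes, adjusted p = 0.00908, and adjusted p = 0.705 with an estimated correlation). Mycn had a log2 difference of 0.68 (SE 0.16) and the RNA polymerase I subunit gene Polr1b one of 0.61 (SE 0.15). That call was lost under median scaling (0.71), cyclic loess (0.0501), the deposited table (0.729) and without embryo 16 (0.0769). The Myc score of heterozygous embryo 10, 0.223, was above those of all homozygous embryos (0.0846, 0.037 and 0.113). Ribosomal protein genes passed as higher, with a median difference of 0.04. Of 48 measured members 0 passed adjusted over the list alone or over all genes (adjusted p = 0.00908, and adjusted p = 0.649 with an estimated correlation). The direction of this list, which camera sets against other probes, turned to lower under median scaling (0.0445) and in the deposited table (0.0465). The call was lost without embryo 16 (0.262) and with array weights (0.0969). The signs of its members Rpl38 (0.23, to -0.16 and -0.20) and Rpl8 (0.38, to -0.01 and -0.04) turned in the same 2 settings, but both stayed above the median of all probes. The median of all probes was -0.06 here, -0.22 under median scaling and -0.25 in the deposited table. The differences in expression given here are not adjusted for that centre, so each is to be read against it.

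Markers of several differentiated cell types were lower in homozygous embryos. Skeletal muscle genes were lower, with the troponin gene Tnnt3 at -0.60 (SE 0.13), the perinatal myosin gene Myh8 at -0.78 (SE 0.22) and the muscle regulator Myog at -1.09 (SE 0.31). Of 20 measured members 4 fell adjusted over the list alone and 0 over all genes (adjusted p = 0.0104, and adjusted p = 0.649 with an estimated correlation). The muscle score of heterozygous embryo 10, -0.232, was below those of homozygous embryos 2 and 7 (-0.147 and -0.201). Neuron genes were lower, with Neurod4 at -0.54 (SE 0.20, or -0.347 without embryo 16) and the growth cone gene Gap43 at -0.32 (SE 0.13). Of 28 measured members 0 passed adjusted over the list alone or over all genes, with 26 of a negative sign (adjusted p = 0.00908, and adjusted p = 0.705 with an estimated correlation). Without embryo 16, whose neuron score of -0.51 was the lowest, the neuron call was lost (0.0769), and the neuron score of heterozygous embryo 10, -0.406, was below those of homozygous embryos 2 and 7 (-0.04 and -0.159). Macrophage and myeloid genes were lower, with the IgG receptor gene Fcgr1 at -1.72 (SE 0.28, adjusted p = 0.0708), Lyz2 at -1.14 (SE 0.35) and Mrc1 at -2.22 (SE 0.80), or -1.29 without embryo 7. Fcgr1 was above background in 1 and Mrc1 in 2 of the 3 homozygous embryos. Of 17 measured members 1 fell adjusted over the list alone and 0 over all genes (adjusted p = 0.0487, and adjusted p = 0.705 with an estimated correlation). This last call was lost without embryo 2 (0.311), 3 (0.0867), 7 (0.148), 13 (0.334) or 15 (0.184). It was also lost under median scaling (0.189), in the deposited table (0.21), with probes present on all 8 arrays (0.172), with the Y-linked covariate (0.123), with the floor at the 1st percentile (0.0514) and with marked spots kept (0.0509). The macrophage score of heterozygous embryo 10, -1.04, was below those of the 3 homozygous embryos (-0.46 ± 0.05, SD, n = 3).

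**Figure D3:**
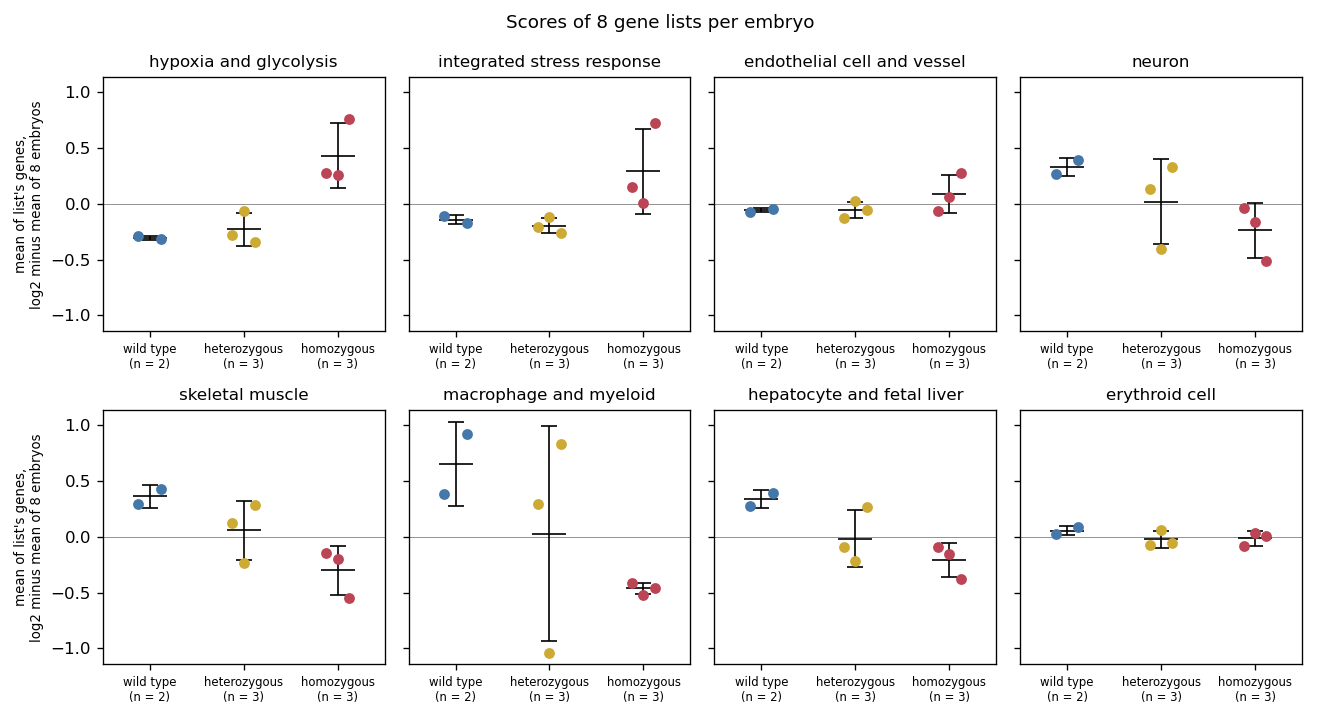
Score of 8 gene lists in each embryo, as the mean over the list's genes of the log2 value minus that gene's mean over the 8 embryos. Each point is 1 embryo, the wide bar is the mean and the whiskers are 1 SD. The hypoxia and glycolysis score is above 0 in the 3 homozygous embryos (0.27, 0.26 and 0.76) and below 0 in the 5 others, and embryo 10 has the lowest macrophage score (-1.04).

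In this comparison 9 lists passed camera, and 7 of the 56 splits of the 8 embryos into 3 and 5, the real one included, gave at least as many. Fry in 1 direction called 2 lists here, hypoxia and glycolysis (0.0393) and haematopoietic progenitor (0.0377), and 0 in each of the 3 other comparisons. The 8 other lists past camera had fry adjusted p-values from 0.0954 to 0.391 in 1 direction. In the exact test of the list score, integrated stress response, cartilage, haematopoietic progenitor, oxidative phosphorylation, p53 and visceral endoderm lists also reached p = 0.0357 (adjusted 0.168). Among the others past camera, skeletal muscle had an exact p of 0.107, neuron, macrophage, endothelial and ribosomal lists 0.143, and cardiomyocyte and Myc lists 0.286. The remaining 24 of the 33 lists did not pass. Among blood lineages, where loss of Rbm15 has been studied in the adult, the erythroid list had an adjusted p of 0.902 (27 measured), the megakaryocyte list 0.992 (13 measured) and the haematopoietic progenitor list 0.249 (13 measured, 1 fallen adjusted over the list alone). The embryonic globin gene Hbb-y, whose spots were saturated, was at 15.07 ± 0.13 (SD, n = 3) in homozygous and 15.08 ± 0.19 (n = 5) in the other embryos, and the globin list had an adjusted p of 0.902 with 3 genes measured. Among RNA processing lists, mRNA export and the Spen family had an adjusted p of 0.992 (28 measured), splicing factors 0.642 (33 measured) and m6A methylation 0.0883 (11 measured, 2 risen adjusted over the list alone, 1 of them Rbm15b). The sign of Rbm15b turned under median scaling, where it stayed above the median of all probes. Liver markers had an adjusted p of 0.29 (19 measured, 2 fallen adjusted over the list alone), with the plasma carrier Ttr at -1.26 (SE 0.22, adjusted p = 0.0855) and Afp at -0.84 (SE 0.30). Visceral endoderm genes had an adjusted p of 0.171 (11 measured), and their member Dab2 was at 8.90 ± 0.09 (SD, n = 3) against 8.96 ± 0.15 (n = 5). Trophoblast and decidua genes had an adjusted p of 0.171 (14 measured, 1 risen and 1 fallen adjusted over the list alone), with Tfap2c at 8.32 ± 0.05 (n = 3) against 8.18 ± 0.34 (n = 5). The Xist and Y-linked list had an adjusted p of 0.879, and its member Kdm5d was at 7.04 ± 1.02 (n = 3) against 7.21 ± 0.68 (n = 5). Cartilage, cell cycle, cholesterol synthesis, Hox, immediate-early, interferon, kidney and gonad, lens, neural crest, neural progenitor, Notch, oxidative phosphorylation and p53 lists had adjusted p-values of 0.992, 0.171, 0.609, 0.251, 0.344, 0.251, 0.643, 0.3, 0.902, 0.902, 0.423, 0.265 and 0.738. The median difference was negative while camera gave the direction as higher in the globin, erythroid, immediate-early, neural crest, neural progenitor and Notch lists, and the reverse held in the megakaryocyte list.

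Against wild type embryos alone, homozygous embryos had 3 named genes past the threshold. Ccdc28b fell by 4.33 (SE 0.29, adjusted p = 0.00479), from 8.57 ± 0.02 (SD, n = 2) to 4.24 ± 0.55 (n = 3), and Trnau1ap fell by 1.86 (SE 0.16, adjusted p = 0.016). Fcgr1, the high-affinity IgG receptor of myeloid cells, fell by 2.20 (SE 0.23, adjusted p = 0.0484). Ccdc28b and Fcgr1 were each above background in only 1 of 3 homozygous embryos, and over the alternatives their changes ranged from -4.58 to -2.55 and from -2.32 to -0.785. Fcgr1 lies on chromosome 3, which also carries Rbm15. Of the unnamed probes, GE114254 was at least 20.5-fold lower (adjusted p = 0.0044), GE102200 fell by 2.40 (SE 0.14, adjusted p = 0.0044), GE1394148 was at least 4.83-fold higher (adjusted p = 0.0484) and GE1568032 was at least 11.3-fold higher (adjusted p = 0.00987). Trim62 at -2.35 (SE 0.31, adjusted p = 0.103) and the protease gene Ctsk, also on chromosome 3 and above background in 1 of 3 homozygous embryos, at -1.56 (SE 0.20, adjusted p = 0.0936) did not pass. Nor did Chst15 at 0.95, the mitochondrial adenylate kinase gene Ak4 at 1.16, 2310022B05Rik at 2.01, the vascular regulator Nr2f2 at 0.94 and Onecut1 at least 2.31-fold higher, with adjusted p-values of 0.101, 0.121, 0.0777, 0.111 and 0.111.

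For homozygous against wild type 8 of 23387 probes passed, 2 higher and 6 lower. All 8 were without overlap between the groups, which picking by a small p favours, so this adds no support. Among probes not so picked, chance gives it in 20% for 3 embryos against 2. There were 3577 probes (15.3%) at an unadjusted p under 0.05. Without wild type embryo 11 no probe passed in limma (1605 at an unadjusted p under 0.05), 2 passed without embryo 13, 4 without embryo 3, 5 without embryo 15, 21 without embryo 16 and 42 without embryo 7. With only these 2 groups in the fit 0 passed (3042 at an unadjusted p under 0.05), and under cyclic loess 11 of 20 calls were higher. Ccdc28b passed in 19 and Fcgr1 in 10 of 22 alternatives, and Trnau1ap in 17 of 23. All 3 calls were lost without wild type embryo 11 or 13, fits in which 1 wild type embryo is left and is assumed to vary like the other groups.

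Of the lists, 8 passed camera for homozygous against wild type, and none did with an estimated correlation, where each had an adjusted p of 0.565. Hypoxia and glycolysis genes were higher, with Vegfa at 1.73 (SE 0.28), Hk2 at 1.38 (SE 0.22), Bnip3 2.83-fold higher (SE 0.27 on the log2 scale) and Egln1 at 0.69 (SE 0.14). Of 23 measured members 13 rose adjusted over the list alone and 0 over all genes (adjusted p = 3.19e-13). Endothelial genes were higher, with Cd93 at 0.75 (SE 0.17), Sox7 at 0.75 (SE 0.22) and Plvap at 0.62 (SE 0.17), and lost the call without embryo 16 (0.205) and with array weights (0.082). Of 25 measured members 0 passed adjusted over the list alone or over all genes (adjusted p = 0.00643). The integrated stress response was higher, with Chac1 at least 4.09-fold higher and Vldlr at 1.15 (SE 0.41), or at least 2.28-fold and 0.712 without embryo 16, when the call was lost (0.0613), as it was with array weights (0.0569). Of 16 measured members 0 passed adjusted over the list alone or over all genes (adjusted p = 0.00354). Myc targets were higher, with Mycn at 0.70 (SE 0.22), and lost the call under median scaling (0.237) and in the deposited table (0.248). Of 24 measured members 0 passed adjusted over the list alone or over all genes (adjusted p = 0.000362).

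The 4 lists that were lower against wild type were markers of differentiated cells. Neuron genes all had a negative sign, with the microtubule regulators Stmn3 at -1.10 (SE 0.43) and Stmn2 at -0.96 (SE 0.39) and the RNA-binding Elavl4 at -0.77 (SE 0.28). Of 28 measured members 0 passed adjusted over the list alone or over all genes (adjusted p = 0.0002). Skeletal muscle genes were lower, with Myh8 at -1.15 (SE 0.18), Tnnt1 at -0.90 (SE 0.24) and Tnnt3 at -0.72 (SE 0.16). Of 20 measured members 5 fell adjusted over the list alone and 0 over all genes (adjusted p = 0.00175). Macrophage genes were lower, with Mrc1 at -2.75 (SE 1.01, or -1.81 without embryo 7), the complement gene C1qa at -2.43 (SE 0.92), both above background in 2 of 3 homozygous embryos, and Lyz2 at -1.31 (SE 0.45) beside Fcgr1, and lost the call without embryo 2 (0.0557) or 13 (0.178) and with probes present on all 8 arrays (0.12). Of 17 measured members 1 fell both adjusted over the list alone and over all genes (adjusted p = 0.00466). Liver genes were lower, with Alb at -2.45 (SE 0.59), Ttr at -1.47 (SE 0.26), Afp at -1.16 (SE 0.35), Apoa2 at -0.82 (SE 0.21) and Apoa1 at -0.73 (SE 0.17), and lost the call without embryo 7 (0.0706) or 13 (0.101). Of 19 measured members 5 fell adjusted over the list alone and 0 over all genes (adjusted p = 0.0172).

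Homozygous and heterozygous embryos differ by 1 further copy of the low-expression allele, and this comparison also tests whether their differences from wild type are unequal. Ccdc28b fell by 4.33 (SE 0.26, adjusted p = 0.0024), from 8.57 ± 0.17 (SD, n = 3) to 4.24 ± 0.55 (n = 3), with 1 of 3 homozygous embryos above background and a range of -4.58 to -2.55 over the alternatives. Trnau1ap fell by 1.86 (SE 0.14, adjusted p = 0.00867). GE114254 was at least 20.3-fold lower and GE102200 fell by 2.13 (SE 0.13), both with an adjusted p of 0.0024. Trim62 at -2.33 (SE 0.28) and Arrdc4 at -0.75 (SE 0.09) had an adjusted p of 0.106 each and Defa31 at -1.69 (SE 0.22) one of 0.148. Chst15 at 1.07 (SE 0.11, adjusted p = 0.0605) did not pass, nor did Glb1 at 0.70, Zfp451 at 0.74, the cytokine receptor gene Csf2ra at 0.68 and the placental fusion gene Synb at least 2.17-fold higher, each with an adjusted p of 0.21. In all 5 of 23388 probes passed, 0 higher and 5 lower, with 2721 (11.6%) at an unadjusted p under 0.05, and 3 of 10 calls were higher under median scaling, 3 of 9 under cyclic loess and 4 of 12 in the deposited table. Without homozygous embryo 7 the count was 58, without embryo 10 it was 10, and without embryo 16 it was 9.

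Of the lists, 6 passed camera for homozygous against heterozygous and 0 with an estimated correlation, where the smallest adjusted p was 0.636. Hypoxia and glycolysis genes were higher, with Vegfa at 1.47 (SE 0.25), Hk2 at 1.09 (SE 0.20), Bnip3 at 1.26 (SE 0.25) and Egln1 at 0.71 (SE 0.12). Of 23 measured members 10 rose adjusted over the list alone and 0 over all genes (adjusted p = 3.67e-15, and adjusted p = 0.636 with an estimated correlation). The integrated stress response was higher, with Chac1 at least 3.84-fold higher and Vldlr at 1.16 (SE 0.37), or at least 2.14-fold and 0.724 without embryo 16. Of 16 measured members 0 passed adjusted over the list alone or over all genes (adjusted p = 1.43e-05, and adjusted p = 0.636 with an estimated correlation). Endothelial genes (25 measured, adjusted p = 0.00136, and adjusted p = 0.636 with an estimated correlation), with Vwf at 0.93 (SE 0.23), Cd93 at 0.53 (SE 0.16) and Angpt2 at -0.48 (SE 0.16), were higher and lost the call without embryo 16 (0.135). Cardiomyocyte genes (24 measured, adjusted p = 0.00498, and adjusted p = 0.674 with an estimated correlation), with Ankrd1, above background in 1 of 3 heterozygous embryos, at 1.38 (SE 0.48), Myl3 at 0.43 (SE 0.19, or 0.227 without embryo 3) and Sln at -0.59 (SE 0.26, or -0.366 without embryo 16), were higher and lost the call without embryo 3 (0.341) and with the Y-linked covariate (0.0884). Skeletal muscle genes (20 measured, adjusted p = 0.0453, and adjusted p = 0.636 with an estimated correlation), with Tnnt3 at -0.52 (SE 0.14) and Myog at -0.94 (SE 0.34), were lower and lost the call without embryo 3 (0.113), 7 (0.105) or 15 (0.229), with the Y-linked covariate (0.461), with probes present on all 8 arrays (0.0629) and with marked spots kept (0.0803). Heterozygous embryo 10 had a lower muscle score than homozygous embryos 2 and 7, and a higher cardiomyocyte score than all homozygous embryos. Ribosomal protein genes (48 measured, adjusted p = 0.0019, and adjusted p = 0.636 with an estimated correlation) passed as higher, turned to lower under median scaling (0.0188) and in the deposited table (0.0197), and lost the call without embryo 16 (0.135). Their member Rpl8 had a difference of 0.51 (SE 0.18, or 0.324 without embryo 15), and Rpl14 one of 0.35 (SE 0.12) that turned to -0.08 under median scaling and -0.11 in the deposited table. The median of all probes was -0.198 and -0.23 there, so Rpl14 stayed above it. In the endothelial, cardiomyocyte, skeletal muscle and ribosomal lists 0 genes passed adjusted over the list alone or over all genes.

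Heterozygous embryos carry 1 low-expression allele, and no probe separated them from wild type at the threshold. The named genes with the smallest p were Gm10413 at 1.85 (SE 0.27) and Vmn1r233 at least 1.42-fold lower, both with an adjusted p of 0.855. Kcnj8, a potassium channel gene of vessel wall cells, was at least 1.91-fold lower, Riiad1 at least 1.70-fold lower, Proser2 at least 1.51-fold lower and the transporter gene Slc5a4a at -0.50 (SE 0.12). The adhesion receptor gene Adgrb1 was at least 1.75-fold higher, Bend6 at 1.13 (SE 0.26), 3830406C13Rik at 1.11 (SE 0.23) and Tcte3 at 0.69 (SE 0.16), and all of these had an adjusted p of 1. The unnamed probe GE1568032, picked out after its values were seen, was not above background in either wild type embryo (3.65 ± 0.07, SD, n = 2) and stood at 7.36 ± 0.47 (n = 3) in heterozygous embryos (adjusted p = 0.106). Limma called 0 of 23387 probes, 538 (2.3%) had an unadjusted p under 0.05, and the smallest adjusted p was 0.1063. Without embryo 10 the count was 3.

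Of the lists, 5 passed camera for heterozygous against wild type and 0 with an estimated correlation, where each of the 5 had an adjusted p of 0.699. In each of the 5 lists 0 genes passed adjusted over the list alone or over all genes. Liver genes were lower (19 measured, adjusted p = 4.18e-05), with Alb at -1.30 (SE 0.59) and Apoa2 at -0.55 (SE 0.21). Neuron genes were lower (28 measured, adjusted p = 4.18e-05), with Elavl4 at -0.50 (SE 0.28) and Scg3 at -0.59 (SE 0.28). Macrophage genes were lower (17 measured, adjusted p = 0.00175), with Fcgr1, above background in 2 of 3 heterozygous embryos, at -0.80 (SE 0.23) and Cd14 at -0.64 (SE 0.54), and skeletal muscle genes were lower (20 measured, adjusted p = 0.00438), with Myh8 at -0.62 (SE 0.18) and Tnnt1 at -0.57 (SE 0.24). Myc targets were higher (24 measured, adjusted p = 0.000989), with the nucleolar genes Nop2 at 0.22 (SE 0.13) and Mybbp1a at 0.28 (SE 0.13). Without heterozygous embryo 10 the neuron (0.201), skeletal muscle (0.201), macrophage (0.974) and Myc (0.537) calls were lost, and without wild type embryo 13 the macrophage (0.317), skeletal muscle (0.0926) and Myc (0.163) calls were lost. With probes present on all 8 arrays the macrophage call was lost as well (0.223). Without embryo 10 the differences were -0.747 for Alb, -0.224 for Elavl4, -0.32 for Scg3, 0.143 for Nop2 and 0.178 for Mybbp1a. Cd14 was at -0.359 without embryo 3, Myh8 at -0.35 without embryo 13, and Nop2 at 0.337 without embryo 11 and 0.109 without embryo 13. The hypoxia and glycolysis list did not pass (23 measured, median difference 0.12, adjusted p = 0.157).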

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

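The counts over other splits of the embryos were planned for the numbers of probes. The splits for the lists, and the tests of embryo 16 and tissue make-up, were chosen after the result was seen. In 88 groups tested for 1 embryo far from the others, 10 were marked, and chance marks about 1 in 20.

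Homozygous embryo 16 gave 3 of the marked values. Its median intensity was 87.9 against 48.3 to 61.5 in the other 7 embryos, 26619 probes were above background against 22526 to 23721, and 1634 probes were left out as contaminated, irregular or masked against 206 to 616. The 95th percentile of its negative control spots, which take no part in any comparison, was also high, at 117 against 14.3 to 30.4.

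The 25 probes that separate homozygous from the other embryos were set against other splits. Of the 56 splits into 3 and 5 embryos, 2 gave as many probes, the real split with 25 and 1 other with 42, a share under 0.05. The real split was not the one with the most probes, and its count ranged from 5 to 314 with 1 embryo left out. Chance assignment is therefore not firmly excluded. The other split set embryos 2, 3 and 7 apart, which the second principal component also did (-38.1, -14.3 and -26.6, against 10.7 to 20.2). This grouping joins homozygous embryos 2 and 7 with heterozygous embryo 3, so it overlaps in part with genotype. Its source was not tested. For homozygous against heterozygous, 3 of the 10 splits gave as many probes, with 5 in the real split and 26 in the highest other. So few splits cannot give a share under 0.05. For the 9 lists past camera in homozygous against the other embryos, 7 of the 56 splits gave as many, up to 12, so chance assignment cannot be excluded for that number.

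The hypoxia and glycolysis score of heterozygous embryo 10, -0.0636, was far above those of the other non-homozygous embryos (-0.345 to -0.277). The higher level of this list in homozygous embryos was weighed against chance, the array of embryo 16 and tissue make-up. Only 1 of the 56 splits, the real one, gave a camera p as small with the list higher (median difference 0.632, against 0.508 in the highest other). The same held for a p as small in any of the 33 lists (6.01e-17, against 8.54e-16 in the next split). The share of splits was thus under 0.05, by a narrow margin. The list and this measure were chosen after the result was seen, so these splits do not exclude chance. Camera with an estimated correlation did not pass (adjusted p = 0.649). The planned exact test of the score did not pass either (adjusted p = 0.168). It stood at the smallest p that the design allows (0.0357), so it could not have passed on the strength of this list alone. Embryos 2 and 7 argue against the array of embryo 16 as the whole cause, since their scores (0.27 and 0.26) lay above those of all non-homozygous embryos. The arrays of embryos 2 and 7 were also brighter than those of all non-homozygous embryos. An effect of array brightness shared by the homozygous embryos was not tested and cannot be told apart from genotype. Without embryo 16 the list still passed camera at the preset correlation (adjusted p = 2.71e-12, median difference 0.40). With the mean score of the neuron, muscle, macrophage and liver lists as a covariate its mean difference was 0.508 (SE 0.144) against 0.69 (SE 0.139) without. The slope of the covariate was -0.377 (SE 0.187). Heterozygous embryo 10 had the same tissue score as embryo 16 (-0.476). Its hypoxia score was still below those of embryos 2 and 7, whose tissue scores were -0.172 and -0.259. Part of the difference may thus follow tissue make-up. The 4 tissue lists were chosen after the list results were seen. The covariate covers only the tissues they mark, so other differences in tissue make-up stay open. A response to low oxygen or altered metabolism in homozygous embryos may be the source, a hypothesis that stays beside delayed development and the time between dissection and freezing, which were not tested; the list also passed with the Y-linked level as a covariate.

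Single genes and other lists gave the remaining marked values. The cartilage and limb score of wild type embryo 13 was 0.15 against 0.01 to 0.04 in the other non-homozygous embryos, and its haematopoietic progenitor score was 0.11 against 0.04 to 0.05. Heterozygous embryo 10 was low in Myog (6.99 against 7.85 to 8.20) and in Mrc1 (4.26 against 6.54 to 6.97). Heterozygous embryo 15 was low in Zfp451 (9.16 against 9.38 to 9.45) and in Hbb-y (14.7 against 15.1 to 15.2).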

How the results depend on the processing

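Keeping marked spots and leaving out embryos 10 and 16 together were chosen after seeing the data. No paired analysis was possible because no embryo number is shared between genotypes. A slide or scan block was not run because no slide or scan batch holds over 1 array. The order of the embryo numbers was not used as a block. The cause of each difference below was not tested except where fewer arrays or more probes enter by construction. For homozygous against the 5 others, 25 probes became 39 under cyclic loess, 45 in the deposited table, 43 with the floor at the 20th percentile, 85 with normexp, 6 without a filter, 50 with probes present on all 8 arrays, 99 with array weights, 118 with a trended prior, 62 with the Y-linked covariate and 70 without embryos 10 and 16, and ranged from 5 to 314 with 1 embryo left out. For homozygous against wild type, 8 probes became 27 under median scaling, 20 under cyclic loess, 27 in the deposited table, 5 and 16 with floors at the 1st and 20th percentiles, 36 with normexp, 4 without a filter, 0 with only those 2 groups in the fit, 186 with array weights, 48 with a trended prior, 5 with marked spots kept and 33 without embryos 10 and 16, and ranged from 0 to 42 with 1 embryo left out. For homozygous against heterozygous, 5 probes became 10 under median scaling, 9 under cyclic loess, 12 in the deposited table, 11 with normexp, 16 with a trended prior and 33 without embryos 10 and 16, and ranged from 4 to 58 with 1 embryo left out. For heterozygous against wild type, 0 probes became 2 under median scaling, 1 under cyclic loess, 2 in the deposited table, 1 with array weights, 1 with a trended prior and 9 without embryos 10 and 16, and ranged from 0 to 3 with 1 embryo left out. The hypoxia and glycolysis list, homozygous against others, passed in every alternative but camera with an estimated correlation (0.649), and its adjusted p ranged from 6.01e-18 to 2.71e-12 with 1 embryo left out. Ribosomal proteins turned to lower under median scaling (0.0445 against others, 0.0188 against heterozygous) and in the deposited table (0.0465 and 0.0197). Against wild type, heterozygous embryos turned in the hypoxia list with the Y-linked covariate (0.943) and in the macrophage list without embryos 10 and 16 (0.954). Without embryos 10 and 16 the endothelial (0.152) and integrated stress response (0.066) calls, homozygous against wild type, were lost, as were those of ribosomal proteins against others (0.263) and heterozygous (0.0835) and, heterozygous against wild type, of Myc targets (0.469), neuron (0.176) and skeletal muscle (0.15). Under median scaling and in the deposited table, Rbm15b turned to -0.0184 and -0.0522 (against others) and -0.0432 and -0.0762 (against heterozygous), Rpl38 to -0.164 and -0.197, Rpl8 to -0.00528 and -0.0391 (against others) and Rpl14 to -0.0771 and -0.11. Rbm15b against wild type turned to -0.0161 in the deposited table. Each of these gene values lay above the median of all probes in the same fit, so only the sign turned, not the side of that median. Of the other values of named genes over all alternatives, 2781 kept their direction and side of the threshold, 148 lost a call and 107 gained one, and for lists 606 kept both and 132 lost a call. Probes near background are limited by the floor: the change of GE114254 ranged from -6.73 to -2.71 against others, and that of Rpp40 from -2.77 to -0.441.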

Other observations

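The fry tests were planned, and the tests on chromosomes 3 and 4 were chosen after the result was seen. Of the 24 lists that did not pass camera in homozygous against the 5 other embryos, 10 had a fry adjusted p under 0.05 in either direction and 1 in 1 direction. Fry asks whether a list's genes change, without setting them against other genes, and 20% of all probes had an unadjusted p under 0.05 here. Oxidative phosphorylation genes had a negative sign in 27 of 32 members, with a fry adjusted p of 0.00101 in either direction and 0.0954 in 1 direction, and their score was -0.07 ± 0.03 (SD, n = 3) in homozygous against 0.02 ± 0.04 (n = 3) in heterozygous and 0.08 ± 0.04 (n = 2) in wild type embryos. Haematopoietic progenitor genes had a fry adjusted p of 0.0377 in 1 direction, with 10 of 13 members of a negative sign and a median difference of -0.11. Hox genes had a negative sign in 23 of 31 members, 3 of them fallen when adjusted over the list alone, with a median difference of -0.12, against -0.06 over all probes. Their fry adjusted p was 0.039 in either direction and 0.182 in 1 direction, so no common direction was shown. The other lists with such a p in either direction were erythroid (0.0276), splicing factors (0.0364), trophoblast and decidua (0.0364), cartilage and limb (0.0402), liver (0.0402), mRNA export and the Spen family (0.0421) and m6A methylation (0.0437), and their p in 1 direction lay between 0.182 and 0.563.

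The unnamed probe GE1568032 followed the genotype labels, a feature picked out after its values were seen. It was at 3.70 and 3.60, not above background, in the 2 wild type embryos, at 7.05, 7.13 and 7.91 in the heterozygous embryos and at 7.40, 8.03 and 8.29 in the homozygous embryos, so every embryo with a copy of the altered allele lay above every embryo without one. The log2 difference between homozygous and heterozygous embryos was 0.54 (SE 0.29, adjusted p = 0.478). The gene that this probe measures is not known here.

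Ccdc28b, Trnau1ap and Trim62 lie near each other on chromosome 4, away from Rbm15 on chromosome 3, and all 3 fell in homozygous embryos. The 39 other tested genes between them had a median log2 change of -0.114, 34 of them within 0.5 of 0, which argues against a loss of the whole stretch, although Iqcc among them was at 1.13. For Ccdc28b and Trnau1ap, which also passed against wild type alone, an equal step down with each altered copy of the allele would put heterozygous embryos at a mean of -0.789, and they were at 0.00175 (SE 0.164), while for Trim62 (-0.0236) such a step stays open, because it was picked against heterozygous and wild type embryos together, which favours genes in which those are alike. A DNA variant at this stretch that the 3 homozygous embryos carry in both copies, whether it lowers the transcripts or only the binding of the probes, is a candidate explanation, as is a dependence on Rbm15 that shows only when both copies are altered. A variant would leave heterozygous embryos unaltered only if they did not carry it or if 1 copy had no effect. Rbm15 lies on another chromosome, so nothing known here ties such a variant to the genotype groups. Neither explanation was tested further, because no genotype of chromosome 4 is known for these embryos.

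Chromosome 3, which carries Rbm15, held 11 of its 551 tested genes with an unadjusted p under 0.001 for homozygous against wild type, 4 higher and 7 lower, against 47 of 10451 on other chromosomes (two-sided Fisher's exact p = 0.00012). The test was set on windows first: the 20, 50, 100 and 200 tested genes nearest to Rbm15 held 0, 1, 3 and 8 such genes, with adjusted p-values over 12 tests of 1, 0.559, 0.0942 and 0.000109, and the whole chromosome was taken after those were seen. Against the 5 other embryos 7 genes of chromosome 3 and 85 of the others passed the same limit (Fisher's exact p = 0.228), and genes are not independent replicates. DNA carried along with the altered allele from the strain in which it was made may account for part of the excess against wild type, including Fcgr1 and Ctsk, which lie among the 11. The share of such genes did not rise toward Rbm15, at 0, 2, 3 and 4% from the narrowest to the widest window. This does not speak for that explanation, although the counts are small. For heterozygous against wild type, 0 of the 551 genes and 2 of the 10451 others passed this limit. Whether both copies must be altered stays open, since the median ratio of heterozygous to homozygous change was 0.352 over the 11 genes against 0.237 (quartiles 0.0717 and 0.493) over the 47 others, both groups share the 2 wild type arrays, and the limit for this ratio was changed after a first value was seen.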
